A study of Homo sapiens with 13 samples.

How the data were processed

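The data were 13 Agilent Human 8x60K 2-colour arrays of total RNA from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Each array compared a treated RNA with its control RNA, 1 in Cy3 and the other in Cy5. There were 3 treatments. UNC0638, a small-molecule inhibitor of the histone H3 lysine 9 methyltransferases G9a (gene EHMT2) and GLP (gene EHMT1), was given at 1 µM for 48 h and compared with its solvent DMSO in 5 biological replicates, of which 1 and 2 were hybridised in both dye orientations and 3 to 5 with the treated RNA in Cy5 alone. An siRNA against WIZ, a zinc finger protein that binds G9a and GLP, was compared with a control siRNA after 72 h in 2 biological replicates, each in both dye orientations. An siRNA against G9a was compared with control siRNA after 72 h in 2 biological replicates with the treated RNA in Cy5 alone. The siRNAs were delivered with a lipid reagent. Separate replicates are named as biological in the labels, and the labels do not say whether the siRNA treatments shared control RNA, which would add to any likeness between them.

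Spot and background intensities, as deposited by the authors, are mean and median pixel brightness per channel before any correction, per the file headers. The files also hold a log2 ratio of the channels, which the authors made by background subtraction and a normalization that depends on brightness, per the file headers. A table for the whole series holds the authors' processed log10 ratios. Its values were set against the log2 ratio of each array's own file, turned to treated over control. They gave control over treated on 8 arrays (r from -0.877 to -0.918) and treated over control on 5 (r from 0.925 to 0.971), and were turned accordingly. Its slopes on the log2 scale ranged from 0.301 to 0.432 in size. The medians of its 13 columns were 0, -0.00301, 0.00794 and 0.00818 for UNC0638 replicates 1 and 2 in the first and the swapped orientation, -0.00413, -0.01, 0 and 0.0032 for WIZ siRNA in the same order, -0.00359, -0.00609 and -0.00882 for UNC0638 replicates 3 to 5, and 0.00178 and -0.00027 for G9a siRNA. What was done to centre or filter these values is not given in the sources used here. Software, scanner settings, slide and scan batch are likewise not given in the sources used here.

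The median spot brightness ranged from 194 to 415 in Cy3 and from 151 to 638 in Cy5, over local backgrounds of 28 to 30 and 45 to 68. Between 47.83% and 91.36% of probes were well above background in the treated RNA, and 57.54% to 92.72% in the control RNA. The number of arrays limits the precision. The arrays fell into 2 sets by the lowest pixel SD of the Cy3 background, which was 4 or 5 on 8 arrays (UNC0638 replicates 1 and 2 and all WIZ siRNA arrays, called set 1 here) and 11 on 5 arrays (UNC0638 replicates 3 to 5 and G9a siRNA, set 2). This set took the place of the slide, which had been planned as the batch. WIZ siRNA and G9a siRNA lie in 1 set each, and UNC0638 alone spans both.

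Background was corrected with normexp (offset 50) on mean spot and median background intensities over all 62976 spots, followed by loess within each array with weight 0 for the 4259 control spots. Spots of 1 probe were averaged, which left 42405 probes. Every array was turned to treated over control from its dye labels, and the arrays of a dye-swapped pair were averaged, since they hold the same RNA. A probe counted as well above background where its signal exceeded the background median by more than 2.6 background SDs, in place of a detection flag, and was kept where this held on at least 50% of the arrays of at least 1 of the 6 RNA groups. Of the 34619 probes kept, the brightest per gene gave 28435 tested features, 17743 of them with a gene symbol. Symbols came from RefSeq accessions for 25519 probes and from symbols or synonyms for 1486. The file's own symbol was kept for 1622, and 13778 had none. For 801 probes the file lists several symbols, among them those of PCDHB2 (also PCDHB3), PCDHGA8 (further PCDHG genes), XAGE2 (also XAGE2B), IGF2 (also INS-IGF2) and EEF1A1 (also EEF1AL7), so their values are not specific to the gene named. Probe coordinates are those of the files, on build 37.1. A probe below background on every array of a group has only a bound there, and its fold is given as "at least", from normalized channel values that dye bias can reach.

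The 9 biological replicates entered 1 limma fit (lmFit and eBayes) with a mean per treatment and no covariate, which gave 6 residual and 3.33 prior degrees of freedom. With 2 replicates per siRNA, the spread is largely borrowed from the UNC0638 replicates. Each treatment mean was tested against 0 and each pair of treatments by the contrast of their means, which keeps the difference in times (48 h and 72 h) within it. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes below 0.05 are called changed. Errors given as SE are those of the fit. Lists were tested with camera on the same fit at a preset correlation of 0.01, and again with the correlation estimated within each list, adjusted over the 21 lists of a comparison. Members are also counted after p-values were adjusted over the list alone. The 21 lists, fixed before the data were examined, were the G9a/GLP complex and H3K9 methylation machinery, germline and cancer-testis genes, interferon-stimulated genes, cholesterol biosynthesis, serine synthesis and amino acid stress, the unfolded protein response, mitosis and S phase, cell cycle inhibitors and p53 targets, autophagy and lysosome, neuronal genes, clustered protocadherins, HOX genes, imprinted genes, globins, epithelial genes, mesenchymal and matrix genes, hypoxia and glycolysis, metallothionein and oxidative stress genes, heat shock, housekeeping genes and blood cell markers. CDKN1C belongs to 2 of these.

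Genes are named by a rule written before the data were examined. It takes EHMT2, EHMT1 and WIZ; the 10 largest rises and 10 largest falls past the threshold with a symbol, the same direction in every replicate and at least 50% of the log2 ratio left after the dye effect is taken off; up to 4 called members of each list, or the member with the largest ratio where none passed; and for differences between treatments the 5 largest each way. Symbols built from clone or locus numbers were left out, a reading settled after a first look at the data. Some genes that the rule takes are not reported. The gene-specific dye effect was taken from the swapped pairs as the mean of their ratios before turning, and subtracted from the arrays that have no swap.

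Alternatives planned beforehand were no background correction, the authors' log2 ratio and log10 table, Aquantile scaling between arrays, no filter and a stricter filter on dim probes, the dye effect subtracted, all 13 arrays with a dye term, the array set as a term or one set alone, each comparison on its own replicates, the mean of all probes, a prior with trend and robust estimation, a minimum fold of 1.5, each replicate left out, and the replicate number as a block. Because Aquantile changes brightness and not ratios, it hardly tests anything here. Chosen after seeing the data were a fit on the 13956 tested features whose probe sequence the files print and a fit after a loess trend on probe GC (span 0.3) was taken off each array. That check covers 49.1% of the features and says nothing of the others.

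The fit was tested on simulated data with seeded changes among 28435 genes. At log2 sizes of 0.5, 1 and 2, it recovered 73.5%, 98.5% and 100% of them for UNC0638, 38.2%, 84.8% and 95.5% for WIZ siRNA and 48.5%, 80.3% and 97% for G9a siRNA, with 9, 6 and 8 unseeded genes called. With a dye effect added, 52, 5 and 77 unseeded genes were called, and 10, 8 and 16 after the dye effect was subtracted. The simulated noise was independent between genes, had a spread per gene shared by all arrays and held no GC trend. The real replicates differed in spread and in GC trend, so these calls do not measure the error in the real data. R 4.3.3, limma 3.58.1 and data.table (1.17.8) were used, with Python 3.11.15 and matplotlib 3.10.9 for the plots. Saturation was not used here, and no genome sequence was used here.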

Results

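Gene expression was measured in HEK293T cells after the methyltransferases G9a and GLP were inhibited with UNC0638 (5 biological replicates on 7 arrays), after knockdown of the zinc finger protein WIZ (2 biological replicates on 4 arrays) and after knockdown of G9a (2 biological replicates on 2 arrays). G9a and GLP place mono- and dimethyl marks on lysine 9 of histone H3, and WIZ is a partner of both. The comparisons address which genes depend on the activity of the enzymes, on G9a itself and on WIZ. All values are log2 ratios of treated over control RNA, and 28435 features were tested in each comparison. The replicates differed in spread. The SD of log2 ratios over all features was 0.17, 0.168, 0.505, 0.27 and 0.296 in UNC0638 replicates 1 to 5, 0.172 and 0.168 under WIZ siRNA and 0.488 and 0.615 under G9a siRNA.

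The targeted transcripts were lower on every array of their own knockdown. WIZ RNA lay at -2.33, -2.01, -2.2 and -1.93 on the 4 WIZ siRNA arrays, which left 23.1% of the control level (mean -2.12 ± 0.21 SD, n = 2, adjusted p = 0.00148). EHMT2, the gene of G9a, lay at -1.67 and -1.65 on the 2 G9a siRNA arrays, or 31.6% of control (mean -1.66 ± 0.015 SD, n = 2, adjusted p = 0.00231). With the dye effect subtracted this value was -1.37. Its probe has a GC content of 55%, and probes of 50 to 55% GC as a class lay at -0.367 and -0.487 in the 2 replicates, and with the GC trend removed EHMT2 lay at -1.22.

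Neither transcript passed the test in the other treatments. EHMT2 had a mean of -0.175 under UNC0638 (SE 0.083, n = 5, adjusted p = 0.265) and 0.308 under WIZ siRNA (n = 2, adjusted p = 0.585). The WIZ siRNA arrays of EHMT2 gave opposite signs by dye, 1.23 and 0.732 with the treated RNA in Cy3 and -0.56 and -0.17 in Cy5. WIZ had a mean of -0.127 under UNC0638 (adjusted p = 0.563) and 0.0849 under G9a siRNA (adjusted p = 0.766). EHMT1, the gene of GLP, had means of 0.252, -0.111 and 0.26 under UNC0638, WIZ siRNA and G9a siRNA (adjusted p = 0.124, 1 and 0.143). A pair of further EHMT1 probes gave the opposite sign under both siRNAs, at 0.228 and 0.321 for WIZ and -0.633 and -0.568 for G9a. On the genome build of the files the probes lie at chromosome 6, 31848474 to 31848533 (EHMT2), chromosome 9, 140730311 to 140730370 (EHMT1), and chromosome 19, 15532937 to 15532996 (WIZ).

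**Figure D1:**
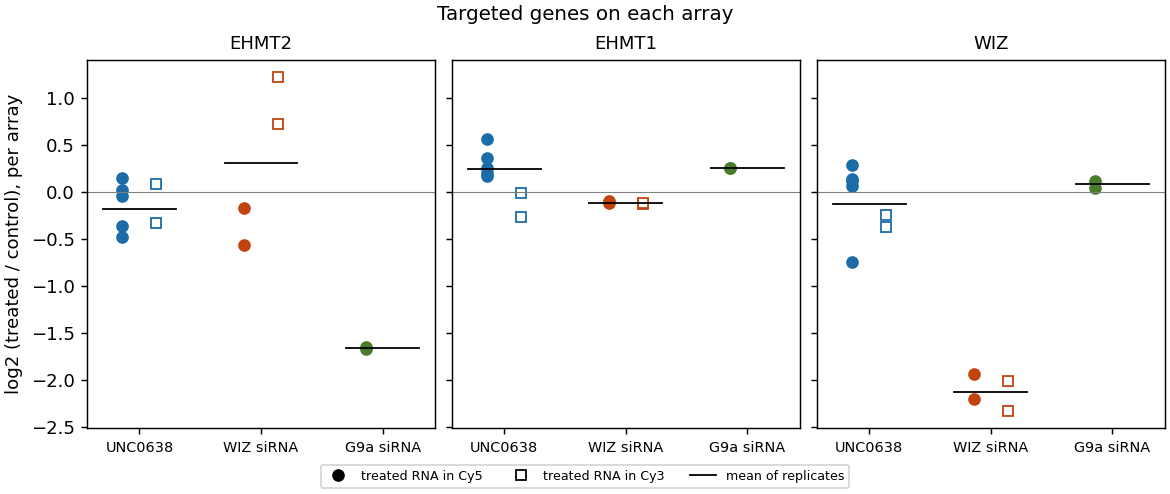
Log2 ratio of treated over control RNA for EHMT2, EHMT1 and WIZ, each point an array, filled with the treated RNA in Cy5 and open in Cy3, with lines at the mean of biological replicates. WIZ lies between -2.33 and -1.93 on its 4 knockdown arrays and EHMT2 at -1.67 and -1.65 on its 2.

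With inhibition of G9a and GLP by UNC0638, the largest rises were in the lipoxygenase gene ALOX15B (2.44, SE 0.17, n = 5, adjusted p = 0.000163), the liver methionine adenosyltransferase gene MAT1A (2.26, SE 0.22) and the long noncoding RNA HULC (1.87, SE 0.15). They were followed by the neuropeptide gene GRP (1.82, SE 0.059, adjusted p = 2.75e-06), the lysozyme-like gene LYG2 (1.62), IRAG1 (1.58), the ryanodine receptor gene RYR2 (1.47), CFAP92 (1.42), the bile acid carrier gene FABP6 (1.41) and the fibrinogen gamma chain gene FGG (1.33, SE 0.052, adjusted p = 8.2e-06). For IRAG1 and FGG the control RNA was well above background on 2 of 7 arrays, so their ratios rest on values near the background. The largest falls were in the zinc finger gene ZSCAN18 (-1.18, SE 0.092, adjusted p = 0.000206) and the imprinted gene PHLDA2 (-1.11, SE 0.13). Falls followed in the neural transcription factor genes NKX6-2 (-1.1, SE 0.10) and HES5 (-1.07, SE 0.11), the zinc finger genes ZIK1 (-1, SE 0.084), ZNF875 (-0.909), ZNF879 (-0.812) and ZNF75A (-0.811), the ligand gene WNT3A (-0.866) and CPNE7 (-0.824). In limma, 1048 features changed, 502 up and 546 down, of which 31 rose and 5 fell by at least 2-fold. All 5 replicates had the same direction for 1039 of them (99.1%). Selection by a test over these same replicates favours such agreement, here and in the siRNA comparisons. Across all features the UNC0638 replicates correlated at 0.0992 (1 with 5) to 0.664 (3 with 4).

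**Figure D2:**
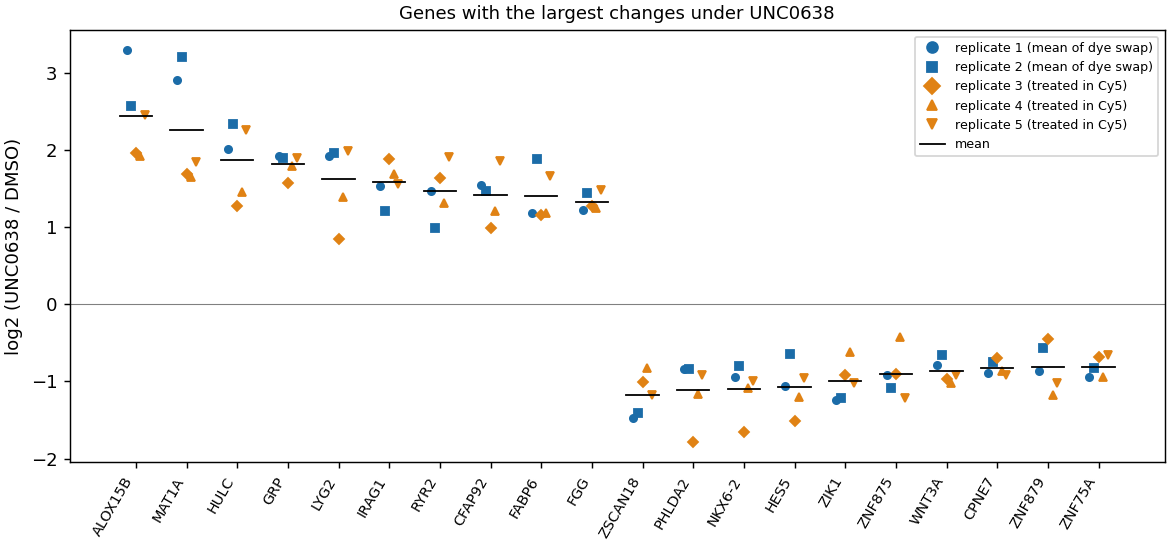
Log2 ratio of UNC0638 over DMSO for the 10 largest rises and 10 largest falls, each point a biological replicate and each line the mean of 5. Every replicate of every gene shown lies on the same side of 0, as the rule for naming genes required. Means run from 2.44 (ALOX15B) to -0.811 (ZNF75A).

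Among the lists, neuronal genes rose with UNC0638. Of 48 measured, 13 rose and 1 fell, and 17 rose and 3 fell with p-values adjusted over the list alone (camera adjusted p = 3.67e-05, and adjusted p = 0.099 with an estimated correlation). BEX1, a small signalling adaptor, rose by 1.18 (SE 0.059), the granule protein genes SCG3 and CHGB by 1.02 (SE 0.11) and 0.933 (SE 0.092), and the stathmin gene STMN2 by 0.841 (SE 0.089). The median of the list was positive in all 5 replicates (0.135, 0.0667, 0.11, 0.0588 and 0.054).

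Genes of serine synthesis and the amino acid stress response rose in 8 of 32 cases and fell in 0 (10 and 0 adjusted over the list alone; adjusted p = 8.46e-05, and adjusted p = 0.133 with an estimated correlation). They included the stress regulator NUPR1 (0.925, SE 0.12), the cystine transporter SLC7A11 (0.864, SE 0.10), and the transcription factors ATF3 (0.433, SE 0.077, with 1 of 4 probes of opposite sign) and ATF4 (0.409, SE 0.079, and 0.158 with the dye effect subtracted). The list median was 0.231, 0.132 and 0.193 in replicates 1, 2 and 4 but -0.0227 and -0.0795 in replicates 3 and 5. In cholesterol biosynthesis 3 of 34 genes rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 0.00193, and adjusted p = 0.25 with an estimated correlation), namely SC5D (0.637, SE 0.14), IDI1 (0.339, SE 0.066) and the sterol carrier STARD4 (0.273, SE 0.052, and 0.073 with the dye effect subtracted). Its median was 0.232, 0.192 and 0.136 in replicates 1, 3 and 4 but -0.0254 and -0.0517 in replicates 2 and 5.

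Germline and cancer-testis genes rose in 5 of 35 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00876, and adjusted p = 0.099 with an estimated correlation). STK31 rose by 0.815 (SE 0.056), XAGE2, with control RNA well above background on 1 of 7 arrays, by 0.555 (SE 0.056) and MAGEC2 by 0.451 (SE 0.057, and 0.291 with the dye effect subtracted), while MAGEB2 fell by 0.519 (SE 0.071). Of 40 interferon-stimulated genes, 7 rose and 1 fell (7 and 3 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.105 with an estimated correlation). The RNA sensor IFIH1 rose by 0.791 (SE 0.081), IFIT2 by 0.588 (SE 0.074), DDX60 by 0.454 (SE 0.045) and IFIT3 by 0.449 (SE 0.072). Blood cell markers, which served as a list of another cell type, rose in 6 of 26 cases and fell in 0 (6 and 1 adjusted over the list alone; adjusted p = 0.00632, and adjusted p = 0.21 with an estimated correlation). They were led by the receptor genes CSF1R (1.16, SE 0.069) and CD33 (1.04, SE 0.075), with LCP1 at 0.733 (SE 0.049) and HLA-DRA at 0.723 (SE 0.090). The list median was negative in replicates 1 and 4 (-0.0275 and -0.0353).

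HOX genes lay lower with UNC0638. Of 38, 0 rose and 2 fell, and 7 fell when adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.0951 with an estimated correlation). HOXB2 fell by 0.566 (SE 0.091) and HOXB4 by 0.293 (SE 0.065). Cell cycle inhibitors and p53 targets fell in 6 of 31 cases and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.025, and adjusted p = 0.21 with an estimated correlation), among them CDKN1C (-0.728, SE 0.14), PLK3 (-0.517), GADD45G (-0.393) and GADD45B (-0.329). Of 26 clustered protocadherins, 3 fell and 0 rose (also 3 and 0 adjusted over the list alone; adjusted p = 0.0277, and adjusted p = 0.21 with an estimated correlation), namely PCDHB2 (-0.482, SE 0.046), PCDHGA8 (-0.43, SE 0.056) and PCDHB11 (-0.298, SE 0.065), where the PCDHB2 probe also matches PCDHB3 and the PCDHGA8 probe further genes of the PCDHG cluster. Of 34 imprinted genes 7 fell and 0 rose, also when adjusted over the list alone, with IGF2 at -0.761 (SE 0.073), DLX5 at -0.432 (SE 0.073), and PHLDA2 and CDKN1C as above, and the list as a whole did not pass (adjusted p = 0.125), though it did with the dye effect subtracted (0.01), in replicates 1 and 2 alone (4.53e-05), without replicate 3 (0.0147) and with the GC trend removed (0.0321). With an estimated correlation it gave adjusted p = 0.255, and adjusted p = 0.151 with the GC trend removed.

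The remaining lists did not pass under UNC0638. Mesenchymal and matrix genes had 4 rises and 2 falls among 28 (7 and 2 adjusted over the list alone; adjusted p = 0.0585), with CCN2 at 0.763, LUM at 0.385, SPARC at 0.364 (0.23 with the dye effect subtracted) and ACTA2 at -0.343. In replicate 3 ACTA2 lay at -0.628, apart from the other replicates. Epithelial genes had 1 fall, in CDH3 (-0.405; adjusted p = 0.0896), globins 1 rise, in HBE1 (0.699; adjusted p = 0.656, with a list median of -0.033 and a mean of 0.036), housekeeping genes 1 rise, in TFRC (0.357; adjusted p = 0.125), and autophagy and lysosome genes 1 rise (adjusted p = 0.77, with a median of -0.0060 and a test leaning up). No member passed in limma among the H3K9 methylation machinery (adjusted p = 0.656; CBX5 0.393, with 6 genes of 31 at an unadjusted p under 0.05), the unfolded protein response (0.27; DERL3 -0.53, 3 of 24), mitosis and S phase (0.77; UBE2C -0.413, 5 of 42), hypoxia and glycolysis (0.393; ERO1A 0.394, 7 of 32), metallothionein and oxidative stress (0.616; MT2A -0.333, 2 of 22) and heat shock (0.27; DNAJB4 0.282, 2 of 22).

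The UNC0638 count came to 538 with the authors' log2 ratio, 467 with their log10 table, 613 without replicate 4 and 1688 in replicates 3 to 5 alone, where replicate 3 correlated at 0.876 and 0.843 with the G9a siRNA replicates. Without replicate 1, the interferon (adjusted p = 0.0685), cholesterol (0.0644), p53 (0.0644) and protocadherin (0.115) lists did not pass, nor did protocadherins without replicate 2 (0.111) or the p53 list without replicate 5 (0.0587). With the log10 table, the germline (adjusted p = 0.532), interferon (0.284), blood cell (0.284), p53 (0.132), HOX (0.101), protocadherin (0.101) and cholesterol (0.0774) lists did not pass. The germline (adjusted p = 0.059) and p53 (0.215) lists did not pass with the dye effect subtracted, nor the p53 list in replicates 1 and 2 alone (0.105).

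Neuronal genes were lower with WIZ siRNA. Neurofilament heavy chain, NEFH, fell by 1.81 (SE 0.084, n = 2, adjusted p = 8.12e-05), the synaptic complexin CPLX1 by 1.32 (SE 0.12), the granule protein gene CHGA by 1.22 (SE 0.081) and the stathmin gene STMN3 by 1.21 (SE 0.17). Of 48 neuronal genes, 8 fell and 1, the synaptic vesicle gene SV2A (0.55, SE 0.095), rose, and 20 fell and 1 rose when adjusted over the list alone (adjusted p = 1.88e-15, and adjusted p = 0.0179 with an estimated correlation). The median of the list was -0.272 and -0.256 on the arrays with the treated RNA in Cy3 and -0.197 and -0.149 in Cy5. Outside this list, VGF (-1.46, SE 0.092), TMEM121B (-1.46), MMP24 (-1.33), FBXL16 (-1.32), DISP2 (-1.24) and KCNC1 (-1.23, SE 0.10) were among the largest falls beside WIZ itself.

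Among the 176 features that changed with WIZ siRNA the rises were fewer, and included LCP1 (0.755, SE 0.077, adjusted p = 0.00373), the RNA-binding protein gene MSI2 (0.708, SE 0.10), HOXA5 (0.697, SE 0.12), FGFBP1 (0.639), TMEM100 (0.628), HOXA10 (0.603, SE 0.097), ZNF703 (0.574), SV2A and the NF-kappaB subunit gene RELB (0.548). Of 38 HOX genes, 3 rose and 0 fell, HOXB6 (0.526, SE 0.082) being the other, and 5 rose and 3 fell when adjusted over the list alone (adjusted p = 4.59e-05, and adjusted p = 0.0179 with an estimated correlation). The HOX median depended on the dye, at 0.357 and 0.287 with the treated RNA in Cy3 and -0.00284 and 0.0548 in Cy5. Arrays of the same WIZ replicate in opposite orientations correlated at -0.501 and -0.362 across genes after turning. Those of UNC0638 replicates 1 and 2 correlated at 0.0408 and 0.0239. A dye effect that adds to the log2 ratio cancels in the average over both orientations.

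In limma 23 of the 176 features were up and 153 down, every one in the same direction in both replicates, and 24 fell by at least 2-fold. With the authors' log2 ratio the count was 29, 0 up and 29 down, and with their log10 values it came to 45, 1 up and 44 down. Without replicate 1 it was 38, and without replicate 2 it was 19, of which 16 and 14 were among the 176. On the WIZ siRNA replicates alone it was 6765, 3538 up and 3227 down, and with a dye term 959, 226 up and 733 down.

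Further lists passed under WIZ siRNA with the preset correlation alone. Cholesterol biosynthesis (adjusted p = 0.000136), serine synthesis and amino acid stress (0.00416), hypoxia and glycolysis (0.0118) and mitosis and S phase (0.0214) lay higher with 0 members passing over all genes in limma, while 7, 2, 4 and 2 members lay higher at an unadjusted p under 0.05, and 2 hypoxia genes lower. The hypoxia list did not pass with the log10 table (adjusted p = 0.0734). Cell cycle inhibitors and p53 targets (0.00874) and clustered protocadherins (0.0103) lay lower, with falls in TP53I3 (-0.593, SE 0.10) and PCDHB2 (-0.507, SE 0.073, with a probe shared with PCDHB3). With an estimated correlation these gave adjusted p = 0.243, and adjusted p = 0.348 for mitosis and S phase, which also did not pass without replicate 1 (adjusted p = 0.0915). Adjusted over the list alone, cholesterol biosynthesis had 1 rise, the p53 list 3 falls and protocadherins 1. Members with the largest ratios that did not pass were MSMO1 (0.436), DDIT3 (0.549), PFKFB4 (0.514), PLK1 (0.364) and CDKN1C (-1.06).

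The other lists had adjusted p from 0.0855 to 0.917 under WIZ siRNA, the lowest for imprinted genes, with 0 members passing and 3 falls adjusted over the list alone, and the highest for the H3K9 methylation machinery, with WIZ as its 1 fall and a median of 0.016 beside a mean of -0.041. With the log10 table the imprinted list passed (camera adjusted p = 0.0169, median -0.165). MAGEB2 fell by 1.05 (SE 0.11) as 1 of 35 germline genes, and LCP1 rose as 1 of 26 blood cell markers. Interferon-stimulated, unfolded protein response, autophagy, globin, epithelial, mesenchymal, metallothionein, heat shock and housekeeping genes had 0 members past the threshold in limma. Their largest ratios were 0.513 for IFI44L, 0.473 for DNAJB9, 0.464 for ATG7, 0.46 for HBG1, -0.417 for CDH3, -0.431 for SPARC, 0.311 for TXNRD1, -0.597 for DNAJB4 and 0.198 for REEP5. Between 0 (housekeeping) and 9 (autophagy and lysosome) of the members of these lists had an unadjusted p under 0.05.

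With knockdown of G9a, changes were far more numerous in the fit of all replicates. With each comparison on its own replicates the counts were 10662 for G9a siRNA, 6765 for WIZ siRNA and 429 for UNC0638. The translation regulator gene CPEB4 rose by 1.95 (SE 0.25, n = 2, adjusted p = 0.00289), MAGI1 by 1.82 (SE 0.25), the elongation factor gene EEF1A1 by 1.8 (SE 0.37) and the sterol methyl oxidase gene MSMO1 by 1.71 (SE 0.27), followed by TAF9B (1.7), ARF6 (1.67), SCAI (1.61), FGF7 (1.6) and PRRG1 (1.6). CLIC4 rose by 1.85. For CLIC4 2 of 3 probes had the opposite sign, and for MAGI1 and PRRG1 1 probe each. The largest falls were in SFTA1P (-5.31, SE 1.0, adjusted p = 0.0054), CCM2L (-5.17, SE 0.98), CISD3 (-5.16, SE 1.0), CELSR1 (-5.11, with 1 of 3 probes of opposite sign), LBX1 (-5.01, SE 0.93), ZNF467 (-4.95), PRR36 (-4.94), NFKBIL1 (-4.94), DIABLO (-4.87) and SRGAP2C (-4.79, with 1 of 2 probes of opposite sign). With UNC0638, replicate 3 had nearly the same values, -5.27 for SFTA1P, -5.00 for CCM2L, -5.24 for CISD3, -4.73 for LBX1 and -4.88 for DIABLO. After a trend on probe GC was removed, ZNF467 lay at -2.29, PRR36 at -2.74 and LBX1 at -4.56, the 3 of these 10 with a probe sequence.

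In limma 9503 features changed with G9a siRNA, 4284 up and 5219 down, in the same direction in both replicates, and 325 rose and 903 fell by at least 2-fold. The ratios of both replicates followed the GC content of the probe (Spearman rho -0.479 and -0.492 across genes, which are not independent replicates), as did UNC0638 replicate 3 (rho -0.428). Probes of more than 60% GC (105 genes) averaged -1.38 and -1.66 under G9a siRNA, -1.46 in UNC0638 replicate 3 and -0.617 in replicate 4, against 0.0844 and 0.0879 under WIZ siRNA. Without G9a siRNA replicate 2 the count was 0 in limma, with 7129 at an unadjusted p under 0.05, and without replicate 1 it was 6015. A dye term gave 4413. All G9a siRNA arrays carry the treated RNA in Cy5 and lie in 1 array set.

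**Figure D3:**
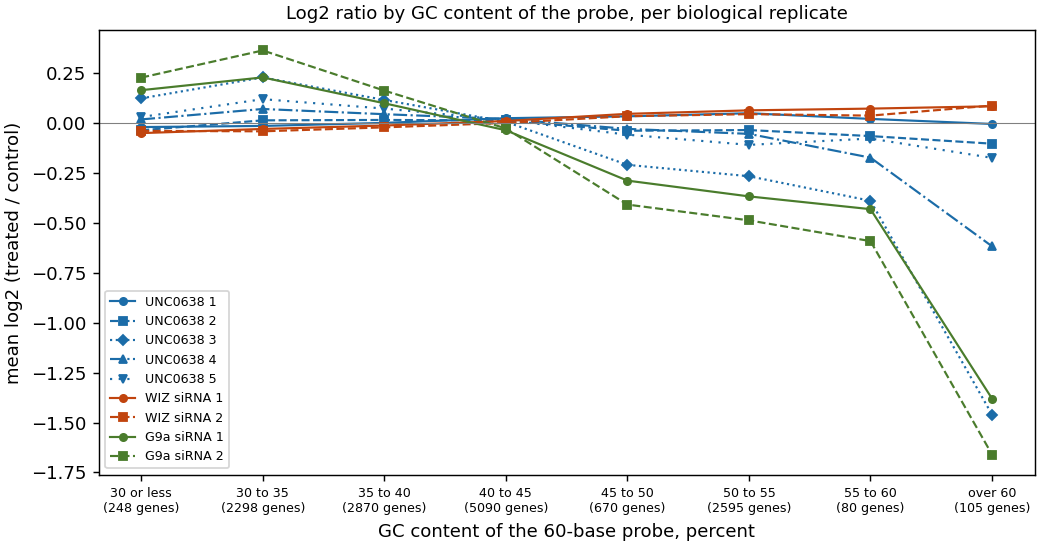
Mean log2 ratio of treated over control RNA for 8 classes of probe GC content, a line per biological replicate, for the 13956 features with a probe sequence. Probes over 60% GC lie at -1.38 and -1.66 under G9a siRNA and at -1.46 in UNC0638 replicate 3, while the WIZ siRNA replicates lie at 0.0844 and 0.0879.

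The metallothionein and oxidative stress list passed under G9a siRNA. Of 22 genes, 11 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.928 with an estimated correlation). The metal-binding metallothionein genes MT2A, MT1B, MT1E and MT1F fell by 1.06 (SE 0.24), 1.05, 1.03 and 0.928 (SE 0.19). The list did not pass with the GC trend removed (adjusted p = 0.283), with the dye effect subtracted (0.0531), with the log10 table (0.496) or without replicate 1 (0.0774).

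The other 20 lists, with adjusted p from 0.581 to 1, had members that passed in both directions, save protocadherins and globins, beside the GC trend given for these replicates. In the H3K9 methylation machinery 9 of 31 rose and 4 fell (9 and 5 adjusted over the list alone), besides EHMT2 with HDAC2 at 0.939, CTBP1 at -0.911 and SUV39H1 at -0.868. Among interferon-stimulated genes 14 of 40 rose and 8 fell (15 and 9), with EIF2AK2 at 1.12 (SE 0.19), IFIH1 at 0.971 (SE 0.13), IFI44L at 0.752 and IRF1 at -0.686. Germline genes had 6 rises and 2 falls among 35 (6 and 0), with TDRD6 at 0.67, TEX14 at 0.579, MAGEA6 at 0.562 and TAF7L, near the background in 1 control RNA, at 0.555. Cholesterol genes had 9 rises and 8 falls among 34 (10 and 11), with MSMO1 at 1.71, MVD at -1.21, LSS at -1.13 and SC5D at 0.937. Serine and amino acid stress genes had 4 rises and 9 falls among 32 (5 and 11), with SLC1A5 at -1.01, AARS1 at -0.855, DDIT4 at -0.81 and SLC7A5 at -0.738.

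Unfolded protein response genes had 6 rises and 6 falls among 24 (6 and 6 adjusted over the list alone), with DERL3 at -1.29, HSP90B1 at 0.779 and HYOU1 at -0.724. Mitosis and S phase genes had 3 and 10 among 42 (3 and 8), with CCNE2 at 1.02, TYMS at 0.984, CDC20 at -0.844 and E2F1 at -0.807. Cell cycle inhibitors and p53 targets had 8 and 12 among 31 (8 and 15), with CDKN1B at 1.38, CDKN1C at -1.19 and PHLDA3 at -0.892. Autophagy and lysosome genes had 12 and 16 among 47 (13 and 18), with MCOLN1 at -1.3, ATG14 at 0.973 and CTSD at -0.967. Neuronal genes had 8 and 8 among 48 (8 and 8), with STMN3 at -1.2, VAMP2 at -0.715, NCAM1 at 0.702 and GPRIN1 at -0.661. With the dye effect subtracted VAMP2 lay at 0.268. HOX genes had 4 and 10 among 38 (4 and 10), with HOXA6 at -1.78, HOXD13 at -1.03, HOXA5 at -0.825 and HOXA3 at 0.757. Protocadherins had 0 and 1 among 26 (0 and 1), PCDHGA8 at -0.431, with a probe that matches further PCDHG genes. Imprinted genes had 6 and 6 among 34 (6 and 6), with UBE3A at 1.27 and PHLDA2 at -1.23. Globins had 0 and 3 among 8 (0 and 3), HBQ1 at -1.07, HBZ, near the background in 1 treated RNA, at -0.745 and HBA2 at -0.367.

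Epithelial genes had 2 rises and 6 falls among 26 (2 and 6 adjusted over the list alone), with EPCAM at 0.999, KRT7 at -0.813 and CDH1 at 0.542. Mesenchymal genes had 5 and 5 among 28 (5 and 5), with SNAI2 at 1.39, TIMP1 at -1.08, TWIST1 at -0.863 and ZEB2 at 0.723. Hypoxia and glycolysis genes had 9 and 10 among 32 (9 and 10), with PFKFB4 at -1.18, ERO1A at 1.12 and ALDOA at -0.872. Heat shock genes had 7 and 5 among 22 (8 and 6), with DNAJB4 at 0.868, HSP90AA1 at 0.754 and HSPB1 at -0.733. Housekeeping genes had 6 and 4 among 29 (6 and 4), with VPS29 at -0.972 and HPRT1 at 0.847. Blood cell markers had 2 and 7 among 26 (4 and 7), with CD4 at -1.7, and TYROBP, which was not above background in the treated RNA, lay at least 1.89-fold lower. Median, mean and test did not share a sign for the cholesterol, unfolded protein response, mitosis, neuronal, protocadherin, imprinted, hypoxia and housekeeping lists.

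Some of these values under G9a siRNA moved by more than 1.5 times with the dye or the GC content of the probe. With the dye effect subtracted, SUV39H1 lay at -0.511, TEX14 at 0.28, IRF1 at -0.442, SLC1A5 at -0.392, AARS1 at -0.497, DDIT4 at -0.478, HSP90B1 at 0.473 and HYOU1 at -0.408. CDC20 lay at -0.532, PHLDA3 at -0.31, CTSD at -0.643, STMN3 at -0.794, HBA2 at -0.187 and HSP90AA1 at 0.363, while PCDHGA8 (-0.708) and HSPB1 (-1.13) lay lower. With the GC trend removed, SUV39H1 lay at -0.421, TEX14 at 0.29, IRF1 at -0.238, MVD at -0.763, SLC1A5 at -0.597, AARS1 at -0.407, HYOU1 at -0.339, CDC20 at -0.428. STMN3 lay at -0.751 and VAMP2 at -0.268. PCDHGA8 lay at -0.0144, HOXA3 at 0.468, HBQ1 at -0.516, CDH1 at 0.254, TIMP1 at -0.633, ALDOA at -0.424, HPRT1 at 0.558, MT1B at -0.606 and MT1E at -0.587.

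Compared directly, WIZ siRNA and UNC0638 differed in neuronal genes. Of 48, 12 were lower with WIZ siRNA and 0 higher (24 and 1 adjusted over the list alone; adjusted p = 1.36e-18, and adjusted p = 0.00641 with an estimated correlation). NEFH lay at -1.81 with WIZ siRNA and 0.308 with UNC0638, a difference of -2.12 (SE 0.10, adjusted p = 8.71e-05). CHGA lay at -1.22 and 0.675, BEX1 at -0.547 and 1.18, and CACNA1B at -0.608 and 0.328, all past the threshold in both treatments. HOX genes were higher with WIZ siRNA in 1 of 38 cases, HOXB2 (difference 0.957, SE 0.17), and 12 were higher and 3 lower when adjusted over the list alone (adjusted p = 8.18e-08, and adjusted p = 0.00641 with an estimated correlation). UNC0638 HOX medians were negative on all 7 arrays. With the dye effect subtracted the difference passed too (camera adjusted p = 3.22e-07), but that step leaves the swapped WIZ siRNA arrays unchanged. It thus says nothing of their HOX medians, which were 0.357 and 0.287 with the treated RNA in Cy3 and -0.00284 and 0.0548 in Cy5. Germline genes (2 lower of 35; adjusted p = 0.00399, and adjusted p = 0.0505 with an estimated correlation), interferon-stimulated genes (2 lower of 40; adjusted p = 0.0134, and adjusted p = 0.0628 with an estimated correlation) and mesenchymal genes (2 lower of 28; adjusted p = 0.0398, and adjusted p = 0.251 with an estimated correlation) were lower with WIZ siRNA. The mesenchymal list did not pass without UNC0638 replicate 1, 2 or 3 (adjusted p = 0.092, 0.0683 and 0.0666) or WIZ siRNA replicate 2 (0.0531). With the log10 table the germline (adjusted p = 0.588), interferon (0.219) and mesenchymal (0.726) differences did not pass.

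**Figure D4:**
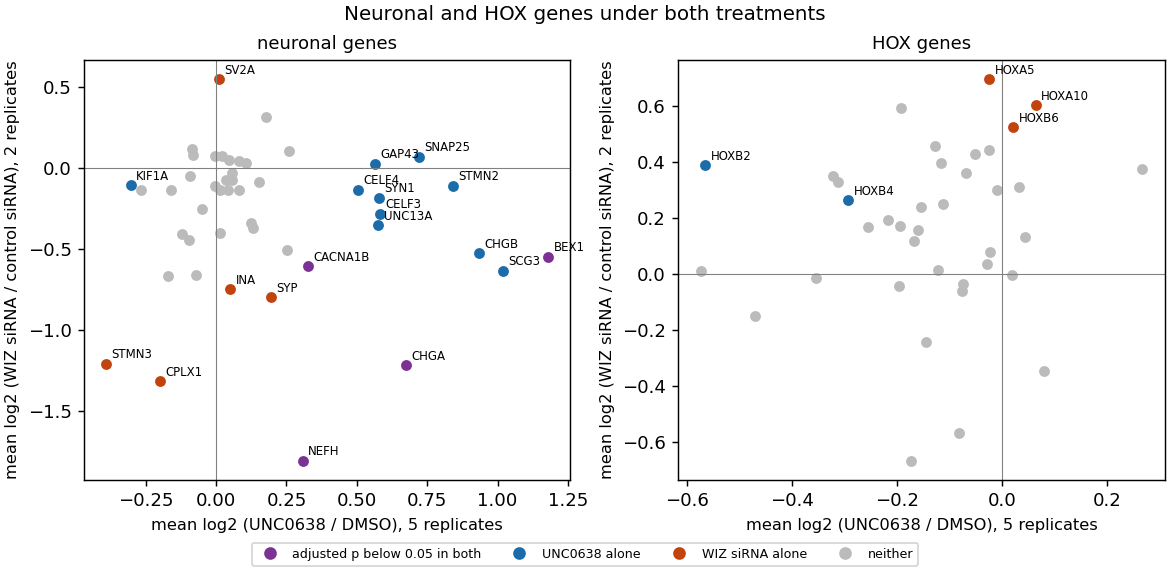
Mean log2 ratio under UNC0638 (x axis, 5 replicates) against that under WIZ siRNA (y axis, 2 replicates) for 48 neuronal and 38 HOX genes, coloured by the treatment in which each passed an adjusted p of 0.05. NEFH, CHGA, BEX1 and CACNA1B lie to the right of 0 and below it, and HOXB2 lies at -0.566 under UNC0638.

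Other large differences of WIZ siRNA minus UNC0638 were in NKX6-2 (1.49, SE 0.20), PLCXD1 (0.878), SP5 (0.822) and TBX18 (0.812), and in ALOX15B (-2.26, SE 0.32), FBXL16 (-2.06, SE 0.15), WIZ (-1.99, SE 0.22) and LYG2 (-1.93, SE 0.29). In limma 240 features differed, 26 higher and 214 lower. The count was 74, 0 higher and 74 lower, with the authors' log2 ratio, 28 without WIZ siRNA replicate 2 and 50 without replicate 1. It was 146, 140 and 149 without UNC0638 replicates 1, 2 and 4.

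The genes that changed under both treatments went both ways. Of the 153 features lower with WIZ siRNA, 23 were higher and 25 lower with UNC0638, where independent draws would give 2.7 and 2.94. Of the 23 higher with WIZ siRNA, 4 were higher and 1 lower with UNC0638 (0.406 and 0.442 expected). All calls came from 1 fit with a shared spread per gene, so genes of low spread are called more readily in every comparison. Independent draws are therefore no fair yardstick for these overlaps or those with G9a siRNA. An excess over them does not show that the treatments share targets. Across all features the correlation of the mean ratios was -0.0439 (rho -0.065), with 0.116 against UNC0638 replicates 1 and 2, which share the array set of WIZ siRNA, and -0.0921 against replicates 3 to 5.

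G9a siRNA and UNC0638 shared direction in most genes that changed in both. Of these, 178 were higher in both (75.6 expected from independent draws), 248 lower in both (100 expected), 29 higher with G9a siRNA and lower with UNC0638 (82.3 expected) and 9 the reverse (92.1 expected). Across features the correlation was 0.678 (rho 0.565), but it was 0.775 against UNC0638 replicates 3 to 5 and 0.0492 against replicates 1 and 2. UNC0638 replicate 3 alone correlated at 0.876 and 0.843 with the G9a siRNA replicates, replicate 4 at 0.5 and 0.499, replicate 5 at 0.181 and 0.197, replicate 2 at 0.136 and 0.125 and replicate 1 at -0.0348 and -0.0554.

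Tested as a difference, 3634 features separated G9a siRNA from UNC0638, 1728 higher and 1906 lower, with 10466 against UNC0638 replicates 1 and 2 alone, and 1 in limma against replicates 3 to 5 alone, where 6292 had an unadjusted p under 0.05. Without G9a siRNA replicate 2 the count was 0 in limma, with 4017 at an unadjusted p under 0.05, without replicate 1 it was 1655, and without UNC0638 replicates 1 to 4 it was 1128, 959, 8013 and 733. PRRG1 (1.65, SE 0.24), CPEB4 (1.57), NOL4 (1.44), SCAI (1.44) and MSMO1 (1.38) were higher with G9a siRNA, and MAP4 (-3.08, SE 0.86), PCSK1N (-2.68, and -1.48 with the GC trend removed), PFKL (-2.61), CD86 (-2.51) and TMEM278 (-2.51) were lower. Serine and amino acid stress genes were lower in 6 of 32 cases and higher in 0 (11 and 1 adjusted over the list alone; adjusted p = 0.0014, and adjusted p = 0.573 with an estimated correlation), and neuronal genes lower in 11 of 48 and higher in 3 (16 and 3; adjusted p = 0.0184, adjusted p = 0.573 with an estimated correlation, and 0.102 without UNC0638 replicate 3). Metallothionein genes were lower in 3 of 22 (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.00696, and adjusted p = 0.641 with an estimated correlation) and blood cell markers in 3 of 26 (4 adjusted over the list alone; adjusted p = 0.00798, and adjusted p = 0.573 with an estimated correlation). With the log10 table the neuronal (adjusted p = 0.292), serine (0.0843), metallothionein (0.134) and blood cell (0.134) differences did not pass, nor did the neuronal one with the authors' log2 ratio (0.0553). The blood cell difference also did not pass with the GC trend removed (camera adjusted p = 0.193).

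Genes that changed with WIZ siRNA overlapped those of G9a siRNA about as often as independent draws would. Of features lower with WIZ siRNA, 33 were lower and 31 higher with G9a siRNA (28.1 and 23.1 expected), and of those higher, 4 were higher and 6 lower (3.47 and 4.22 expected). The correlation across features was -0.199 (rho -0.221). The siRNAs lie in different array sets, joined only through UNC0638. In the direct test, neuronal genes were lower with WIZ siRNA in 14 of 48 cases and higher in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.000794, and adjusted p = 0.27 with an estimated correlation), and metallothionein genes higher in 4 of 22 and lower in 0 (4 and 0; adjusted p = 0.00798, and adjusted p = 0.561 with an estimated correlation). The metallothionein difference did not pass with the log10 table (adjusted p = 0.241) or with the GC trend removed (0.0897). NDFIP2 (-2.3, SE 0.28), WIZ (-2.2, SE 0.26), TAF9B (-2.18), NEFH (-2, SE 0.12) and EEF1A1 (-1.98) were lowest, and SFTA1P (5.47, SE 1.5), CISD3 (5.35), CCM2L (5.31), CELSR1 (5.31) and LBX1 (5.19) highest. In limma 5689 features differed, 3149 higher and 2540 lower with WIZ siRNA, but 2 with the array set as a term. Leaving out a replicate gave 1 in limma without G9a siRNA replicate 2 (6209 at an unadjusted p under 0.05), 3782 without G9a siRNA replicate 1, and 23 and 4 without WIZ siRNA replicates 1 and 2.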

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

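The tests of the 3 patterns weighed here were chosen after the results were seen, except the count of splits of the UNC0638 replicates, which was planned before. Of 95 results tested for a replicate far from the others of its group, 2 were found. Many of the 95 are genes named for a low adjusted p or the same direction in every replicate, which favours genes without such a replicate. The 4.75 that chance would give among results not picked this way is therefore no yardstick here. ACTA2 lay at -0.628 in UNC0638 replicate 3 and between -0.326 and -0.205 in the others. DNAJB4 lay at 0.844 in the same replicate and between 0.056 and 0.27 in the others. Reversing the direction of replicates gave 16 splits of the 5 UNC0638 replicates, too few for a share under 0.05, with 1048 genes in the real split and 0 in the highest other in limma.

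UNC0638 replicate 3 resembled the G9a siRNA replicates more than the other UNC0638 replicates, with correlations of 0.876 and 0.843. A mislabelled G9a siRNA sample would have low EHMT2, but it lay at -0.362 there against -1.66 under G9a siRNA. The mean of UNC0638 replicates 1 and 2 correlated with G9a siRNA at 0.0492, against 0.875 for replicate 3. Replicates 1 and 2 lie in set 1 and G9a siRNA in set 2, so this cannot decide on a shared response to the loss of G9a activity. A trend with the GC content of the probe does not account for the likeness on the features with a probe sequence. There the correlation was 0.8 after the trend was removed and 0.846 before. For the 14479 features without a sequence it stays open. The dye effect of the swapped pairs does not account for the likeness either, since the correlations were 0.866 and 0.818 with it subtracted. With the same dyes in the same set, UNC0638 replicate 5 reached 0.181 and 0.197, and replicate 4 reached 0.5 and 0.499. No swapped pair lies in set 2, so a dye effect particular to that set could not be estimated. What sets replicate 3 apart stays open, and RNA quality was not tested.

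Neuronal genes fell with WIZ siRNA. A dye effect would reverse with the swap, but the list median was negative on all 4 arrays, from -0.272 to -0.149. The list differed between the siRNAs (camera adjusted p = 0.000794, and adjusted p = 0.27 with an estimated correlation), each compared with a control siRNA. NEFH lay at 0.189 and CHGA at 0.396 under G9a siRNA. Of the 8 members that fell, 2 fell there too, STMN3 (-1.2) and CPLX1 (-0.567). The siRNAs lie in different array sets, and with the set as a term the count of features that differ fell from 5689 to 2. Lists were not run with that term, so this contrast cannot decide on a response to siRNA delivery in general, which stays open. Probe GC content does not account for the fall of the 34 members with a probe sequence. Their median was -0.168 after the trend was removed and -0.16 before (camera adjusted p = 2.4e-11, and adjusted p = 0.0355 with an estimated correlation). For the 14 others GC content stays open. An off-target effect of the WIZ siRNA stays open and was not tested.

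Zinc finger genes of chromosome 19 were lower with UNC0638, with a median of -0.235 over 157 genes. GC content does not account for it, as the median was -0.26 with the trend removed. The dye does not either, since the swapped replicates 1 and 2 gave -0.362 against -0.177 in the others. The median was -0.231 over the 147 probes listed with 1 gene symbol. Too few probes were left out to move it far, so this cannot decide on probes that match several genes. Other genes of chromosome 19 had a median of -0.0742, and of -0.0326 with the GC trend removed. No biological explanation was tested.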

How the results depend on the processing

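The fits on genes with a probe sequence and with the GC trend removed were chosen after seeing the data; the others were planned. Over all settings 68 gene counts stayed within 1.5 times the reported one, 46 fell below and 12 rose above it. Of the named genes, 3815 values kept their side of the threshold, 613 lost and 29 gained a call, with the most losses without G9a siRNA replicate 2. Among values with a call in the main fit or the alternative, 2 reversed direction. Direction was not compared where neither passed, and signs could change there. EHMT2 under UNC0638, for example, lay at -0.175 and at 0.00079 with the dye effect subtracted. Of list results, 1593 kept their side, 82 lost and 26 gained a call. Lists were not run with the filters, the set or dye terms, the block, own replicates, the mean of all probes or the prior with trend. In the settings that were run, neuronal and HOX genes under WIZ siRNA passed, and neuronal genes under UNC0638 passed except with the estimated correlation. In set 2 alone the cholesterol (adjusted p = 0.0662), HOX (0.0821), serine (0.0821), blood cell (0.0821), germline (0.147), interferon (0.188) and protocadherin (0.375) lists of UNC0638 did not pass, and on genes with a probe sequence neither did germline (0.054) and interferon genes (0.138, or 0.091 with GC removed). Under UNC0638, calls were gained without a replicate by epithelial (0.0347, replicate 3), mesenchymal (0.0323 and 0.0381, replicates 4 and 5), unfolded protein (0.0484) and heat shock genes (0.0305, both replicate 5). In set 1 alone they were gained by unfolded protein (0.00717), mesenchymal (0.0143) and hypoxia genes (0.031), with no background correction by mesenchymal genes (0.0449) and with the log10 table by globins (0.0423). For WIZ siRNA minus UNC0638, germline and interferon genes did not pass in set 2 alone (0.11 and 0.133) or on genes with a probe sequence (0.0636 and 0.121). With a lone replicate left, that replicate is assumed to vary like the others. The cause was not tested for the values given here, except that fewer replicates, fewer genes or a higher bar are part of some settings. Signal over background limits dim probes, and 47.83% of probes were well above it in G9a siRNA replicate 2.

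For UNC0638 (1048) the count was 538 with the authors' log2 ratio, 467 with their log10 table, 696 with the stricter filter, 1774 with the array set as a term, 1688 in set 2 alone, 429 on its own replicates, 206 (138 up, 68 down, against 502 and 546) at a 1.5-fold minimum, and 613 to 884 with a replicate left out. For WIZ siRNA (176; 23 up, 153 down) it was 29 (0 up, 29 down) with the log2 ratio, 45 (1 up, 44 down) with the table, 959 (226 up, 733 down) with a dye term, 86 with the set term, 6765 (3538 up, 3227 down) on its own replicates and 19 to 38 with a replicate left out. For G9a siRNA (9503) it was 4413 with a dye term, 5600 with the set term, 4586 at 1.5-fold, 6324 on genes with a probe sequence, 6358 there with GC removed, and 0 (limma; 7129 at an unadjusted p under 0.05) to 6015 with a replicate left out.

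For WIZ siRNA minus G9a siRNA (5689) it was 3440 with the log2 ratio, 2187 with the table, 3299 with the dye effect subtracted, 2 with the set term, 10576 on its own replicates, 11147 with the replicate number as a block, whose pairing shares only a number, and 1 to 3782 with a replicate left out. For G9a siRNA minus UNC0638 (3634) it was 1547 with the log2 ratio, 1021 with the table, 2218 with the dye effect subtracted, 688 with the set term, 10466 with UNC0638 in set 1 alone, 1 in set 2 alone, 857 on its own replicates, 2193 at 1.5-fold, 10490 with the block, and 0 to 8013 with a replicate left out. For WIZ siRNA minus UNC0638 (240; 26 up, 214 down) it was 74 (0 up, 74 down) with the log2 ratio, 85 with the table, 145 with the stricter filter, 806 (182 up, 624 down) with a dye term, 157 with the set term, 501 with UNC0638 in set 1 alone, 529 with the block, and 28 to 347 with a replicate left out.

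VAMP2 under G9a siRNA (-0.715) turned to 0.268 with the dye effect subtracted and 0.107 with a dye term. The correlation of WIZ siRNA with G9a siRNA (-0.199) was -0.176 with the table, -0.129 with the dye effect subtracted, -0.133 with the log2 ratio, -0.139 with GC removed and -0.195 to -0.18 with a replicate left out, the latter without WIZ siRNA replicate 2. That of G9a siRNA with UNC0638 (0.678) was 0.0492 with set 1 alone and 0.336 (without UNC0638 replicate 3) to 0.739 with a replicate left out, and that of WIZ siRNA with UNC0638 (-0.0439) was 0.0879 with the dye effect subtracted and 0.116 with set 1 alone.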

Other observations

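The lists in these paragraphs were defined, and their tests chosen, after the data were examined. Their camera p-values were adjusted among themselves within a comparison, not together with the lists fixed beforehand. Being adjusted over fewer lists, they are not comparable with the adjusted p of the fixed lists. For zinc finger genes of chromosome 19 under UNC0638, the unadjusted camera p with an estimated correlation was 0.0165. Zinc finger genes of chromosome 19 were lower with UNC0638. They were picked by symbol (ZNF, ZSCAN, ZKSCAN or ZFP with a number, and ZIK1) and not by function. Of 157 measured, 47 fell and 1 rose (80 and 3 adjusted over the list alone; adjusted p = 2.72e-24, and adjusted p = 0.0495 with an estimated correlation), with medians of -0.396, -0.348, -0.13, -0.197 and -0.195 in the 5 replicates. ZSCAN18 (-1.18, probe at 58595379 to 58595438 of chromosome 19), ZIK1 (-1, 58102876 to 58102935), ZNF875 (-0.909, 37854787 to 37854846), ZNF577 (-0.793), ZNF586 (-0.767) and ZNF256 (-0.722) fell most. Zinc finger genes of other chromosomes had 15 falls and 4 rises among 222 (median -0.0279, adjusted p = 0.402, but a median of -0.0458 and adjusted p = 0.0066 with the GC trend removed), and other genes of chromosome 19 had 29 falls and 9 rises among 728 (median -0.0742, adjusted p = 1.32e-05, and adjusted p = 0.364 with an estimated correlation). With the GC trend removed, the other genes of chromosome 19 had a median of -0.0326 (camera adjusted p = 0.0154). Of 542 zinc finger symbols, 69.9% have a position in the files. With WIZ siRNA the chromosome 19 list had a median of -0.197, with 3 falls and 0 rises (17 and 0 adjusted over the list alone; adjusted p = 1.99e-17, and adjusted p = 0.0981 with an estimated correlation). Under G9a siRNA its median was -0.00859, with 32 falls and 20 rises (adjusted p = 0.996).

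Genes with a symbol that changed with both WIZ siRNA and UNC0638 fell into an opposite and a shared group. Lower with WIZ siRNA and higher with UNC0638 were MMP24 (-1.33 and 0.52), FBXL16 (-1.32 and 0.737), VGF (-1.46 and 0.385), the presynaptic scaffold gene BSN (-1.04 and 0.471), AP3B2 (-0.93 and 0.594), the sodium channel subunit gene SCN3B (-0.906 and 0.477), NMNAT2 (-0.751 and 0.67) and the GABA receptor gene GABBR2 (-0.612 and 0.402). Lower in both were CCND1 (-0.928 and -0.349), WNT3A (-0.772 and -0.866), INHBB (-0.856 and -0.36), DHRS2 (-0.696 and -0.778) and the zinc finger genes ZNF256 (-0.451 and -0.722), ZNF790 (-0.575 and -0.494), ZNF649 (-0.503 and -0.503) and ZNF585B (-0.433 and -0.52). LCP1 (0.755 and 0.733), FGFBP1 (0.639 and 0.954) and CYP4X1 (0.475 and 0.252) were higher in both, and TBX18 (0.532 and -0.28) was higher with WIZ siRNA and lower with UNC0638.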
